A study of Mus musculus with 6 samples.

How the data were processed

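RNA-seq libraries were made from total RNA of frozen mouse blastocysts, 3 developed in vivo and 3 cultured in vitro, with a microscale extraction kit and a transposase-based library kit that does not mark strand, per the labels' protocols. The authors deposited 1 table of raw counts per gene with 49993 genes and 1 column per library, with no gene name repeated. Its columns follow the layout of the counter featureCounts, but the counter, the aligner, the annotation and the strand setting are not given in the sources used here. The submitters' processing notes name FastQC 0.11.2, DESeq2 and the genome build GRCm39. The gene coordinates in the deposited count table, however, equal those of RefSeq genes on GRCm38.p6 for each of the 49589 genes compared, so coordinates are given on GRCm38. Gene lengths were taken from the same table. Because strand was not marked, reads of a gene cannot be told from those of an overlapping antisense gene, and genes with near-identical copies may share counts. PCR copies cannot be told from molecules without molecular identifiers, so intervals and floors cover counting error only.

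Libraries were grouped by their titles, which carry a group and a replicate number. Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filter on low counts by group (14301 genes), libraries were scaled by trimmed mean of M values (TMM), and dispersions were estimated with robust moderation, which gave a common biological coefficient of variation of 0.727. The groups were compared by the two-sided quasi-likelihood F-test in its legacy form, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values were computed on the TMM-scaled library totals, in which ribosomal RNA is included. The log2 CPM used for correlations and principal components has a prior count of 2. DESeq2 1.42.0 and limma 3.58.1 (voom with sample quality weights) were run beside it. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 29 lists with at least 3 measured genes. A fold against a group with 0 counts is a lower bound against 3 counts over the group, and a ratio over 1 to 3 counts carries a 95% exact binomial counting interval.

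Before the data were examined, the tests, 32 gene lists of 901 symbols and the rule for named genes were fixed. The lists cover sirtuins, telomere and NAD+ genes, embryo lineages, other cell types, stress, metabolic and repair pathways, and signs of sample quality. Of the symbols, 4 had no match in the table. Named were the sirtuins and main telomere genes whatever their values, up to 4 members of smallest p from each list, and in each direction up to 12 genes that passed the test with an assigned symbol, a mean of at least 10 CPM and no overlap between groups. Predicted genes, pseudogenes and clone names were left out of this last group by their symbols. Since 0 genes passed, the 5 of smallest p in each direction under the other conditions were named instead. Genes named outside this rule are said to be so. The name of 1 gene called by an added fit is not reported here.

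Each test was first run on simulated counts for the same 14301 genes with 200 changed genes of at least 10 CPM, 100 by 4-fold and 100 by 16-fold. With the dispersions of the real libraries, edgeR recovered 32% of the 4-fold and 94% of the 16-fold changes with 7 false calls, DESeq2 61% and 99% with 75 false calls (31.9% of its calls), and limma-voom 26% and 74% with 2 false calls. With a dispersion of 0.05, each tool recovered 100% of both sizes. The simulated genes were independent and the simulated libraries of a group equally alike, unlike the real ones. These shares therefore do not give the power in the real data.

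Totals of 6918288 to 17643429 counts per library set the precision. A count of 0 in a library allows up to 0.216 to 0.527 CPM (3 counts). No 2 libraries were copies of each other: the chi-square per degree of freedom between in vivo replicates 1 and 2, the closest pair, was 31.5 over 15224 genes with at least 20 counts in the pair, where sampling noise alone gives about 1.

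Alternatives fixed in advance were DESeq2's size factors, scaling by library totals alone, no filter and a stricter filter (at least 5 CPM in at least 3 libraries), each library left out, the replicate number as a block, the other tools, edgeR without robust moderation, protein-coding genes only, X- and Y-linked genes left out, other thresholds, and other correlation measures. Added after the data were seen were fits without ribosomal RNA genes and genes treated as ribosomal-RNA-like, with an offset on gene length, and with edgeR's newer quasi-likelihood form, and further DESeq2 fits. Whether the genes so treated carry ribosomal RNA reads was not tested. A fit with embryo sex as a term was planned only if both groups held both sexes and was not run, since all 3 in vivo libraries carried a Y chromosome. GC content was taken from GENCODE transcripts on GRCm38 and was known for 92.3% of the tested genes. All 6 columns of samples were used.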

Results

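Gene expression was measured by RNA-seq in mouse blastocysts that either developed in the reproductive tract (in vivo group, n = 3 libraries) or were cultured from the zygote to the blastocyst stage (in vitro group, n = 3 libraries). Females of both groups received 10 IU of pregnant mare serum gonadotrophin and, 48 h later, 10 IU of human chorionic gonadotrophin (hCG), which together induce the release of many oocytes, and were mated. In vivo blastocysts were flushed from the uterus on day 3.5. Zygotes of the in vitro group were taken from the oviducts 19 to 21 h after hCG and grown in KSOM, a potassium-enriched culture medium, at 37 °C under 5% CO2. The age of the cultured blastocysts at freezing is not given in the sources used here. The sample descriptions name 1 inner cell mass per library, the cell cluster from which epiblast and primitive endoderm arise, whereas the text on the design speaks of RNA from blastocysts, so the labels leave open whether trophectoderm was part of each sample. Totals were 9174789, 10240704 and 17643429 counts for in vivo replicates 1, 2 and 3, and 6918288, 12735551 and 9212405 counts for in vitro replicates 1, 2 and 3. No label states that the libraries of a group came from separate mothers or litters, so p-values measure the spread between these samples only, which may be partly technical.

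The libraries of each group differed widely from each other. In vivo replicates 1 and 2 were the most similar pair, with a Spearman correlation of log2 CPM across genes of 0.942, whereas in vivo replicate 3 reached only 0.786 and 0.793 with them. In vitro replicate 2 resembled in vivo replicates 1 and 2 more closely (0.873 and 0.857) than in vivo replicate 3 did. The 3 pairs of in vitro libraries had correlations of 0.789 to 0.848, and the 9 pairs across groups had a median of 0.772. The 18S ribosomal RNA gene Rn18s-rs5 took 16.7%, 22.2% and 41.7% of the counts in the 3 in vivo libraries and 36.1%, 35.8% and 40.4% in the 3 in vitro libraries, each with a 95% Wilson interval of at most ±0.0358 percentage points, which covers counting error only. Counts of Y-linked genes and of Xist, the RNA that coats the inactive X chromosome, showed the sex of the embryos. In vitro replicate 2 had 1 Y-linked count and 7494 Xist counts, and the other 5 libraries had 1180 to 1766 Y-linked counts and 8 to 341 Xist counts. All 3 in vivo libraries therefore carried a Y chromosome, so a term for sex could not be set apart from in vitro replicate 2.

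**Figure D1:**
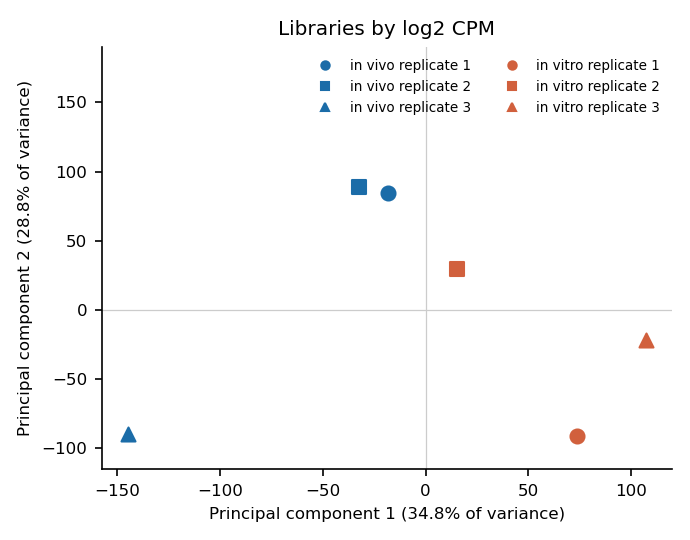
Principal components of log2 CPM of the 6 libraries, with in vivo libraries in blue and in vitro libraries in orange. Component 1 holds 34.8% of the variance and component 2 28.8%, and in vivo replicate 3 lies far from in vivo replicates 1 and 2 on both.

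The first comparison addressed sirtuins, telomere factors and NAD+ metabolism, since the title of the series names Sirt6, NAD+ and telomere shortening. Sirt6, an NAD+-dependent deacylase that acts on chromatin and telomeres, was lower in each of the 3 in vitro libraries than in any in vivo library. It lies on the minus strand of chromosome 10 at 81621787 to 81627792 of GRCm38 and is protein-coding. Its expression was 62.0 ± 16.1 CPM in vivo and 20.6 ± 3.00 CPM in vitro (SD, n = 3 each), from 724, 999 and 683 counts in vivo and 106, 327 and 146 counts in vitro. The log2 fold change, in vitro minus in vivo, was −1.59 ± 0.37 (SE). It did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all 14301 genes tested (adjusted p = 0.315) or adjusted over the 69 measured genes of the 5 study lists (adjusted p = 0.134). Adjusted over the list alone, that of the 6 measured sirtuins, edgeR gave an adjusted p of 0.0116. The study sequenced these libraries to find genes behind telomere shortening, and its title already names Sirt6. An adjustment within its own lists, that over the sirtuins included, is therefore not independent evidence. DESeq2, the tool named in the submitters' processing notes, called Sirt6 lower in vitro (log2 fold change −1.58 ± 0.41, adjusted p = 0.0110), and limma-voom with quality weights gave an adjusted p of 0.0684. The DESeq2 call was lost without in vivo replicate 1 (adjusted p = 0.0681), without in vivo replicate 2 (0.198) and without in vitro replicate 1 (0.0807), in a range of 0.00336 to 0.198 over the 6 libraries left out in turn.

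The other sirtuins overlapped between the groups. Sirt1 was at 44.6 ± 33.7 CPM in vivo and 56.3 ± 36.8 CPM in vitro, and Sirt7 at 7.66 ± 5.76 and 11.2 ± 8.09 CPM (SD, n = 3 each). Sirt2, Sirt3 and Sirt4 had log2 fold changes of −0.44 ± 1.16, −2.32 ± 2.07 and −2.63 ± 1.85 (SE), with Sirt3 at 0 counts in 3 libraries. Sirt5 had 0 to 5 counts per library and Terc, the RNA template of telomerase, 0 to 8, and both were too low to be tested. Of 9 measured members of shelterin and the CST complex, which bind telomere ends, 6 had a positive and 3 a negative log2 fold change and none had an unadjusted p below 0.05. Among them were Terf1 (0.32 ± 0.42), Terf2 (0.62 ± 0.76), Pot1a (0.46 ± 0.72), Acd (−0.83 ± 1.20), Tinf2 (−0.27 ± 0.55) and Terf2ip (0.94 ± 0.53). Terf1 had the opposite sign when libraries were scaled by their totals alone (−0.0400), a scaling that shifted the median gene by −0.31. Tert, the reverse transcriptase of telomerase, was at 2.98, 5.53 and 2.30 CPM in vivo and at 10.5, 9.04 and 4.18 CPM in vitro (adjusted p = 0.688, edgeR). Of 14 telomerase genes, 7 had a positive and 7 a negative log2 fold change, and Naf1, a factor for assembly of the telomerase particle, had an unadjusted p below 0.05 (log2 fold change 1.52 ± 0.52, adjusted p = 0.409). Of 21 genes of telomere replication and recombination, 13 were positive and 8 negative. Atrx, a chromatin remodeller at telomeres, was at 52.3 ± 28.6 CPM in vivo and 121 ± 30.6 CPM in vitro (adjusted p = 0.415). The list of NAD+ metabolism had 19 measured genes, 9 positive and 10 negative. Pnp, a purine nucleoside phosphorylase, was at 29.9 ± 6.91 and 55.3 ± 15.6 CPM (adjusted p = 0.482) and the NAD+ consumer Parp1 at 123 ± 19.9 and 86.0 ± 5.59 CPM (adjusted p = 0.592). No gene of the 5 lists passed edgeR's test adjusted over these lists, against 1 by DESeq2 (Sirt6) and 3 by limma-voom (Atrx, Naf1 and Sirt6). As sets, camera gave adjusted p-values of 0.242 for the sirtuins, 0.855 for shelterin and CST, 0.981 for telomerase, 0.308 for telomere recombination and 0.630 for NAD+ metabolism, whose median log2 fold change (−0.08) and mean (0.23) differed in sign.

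**Figure D2:**
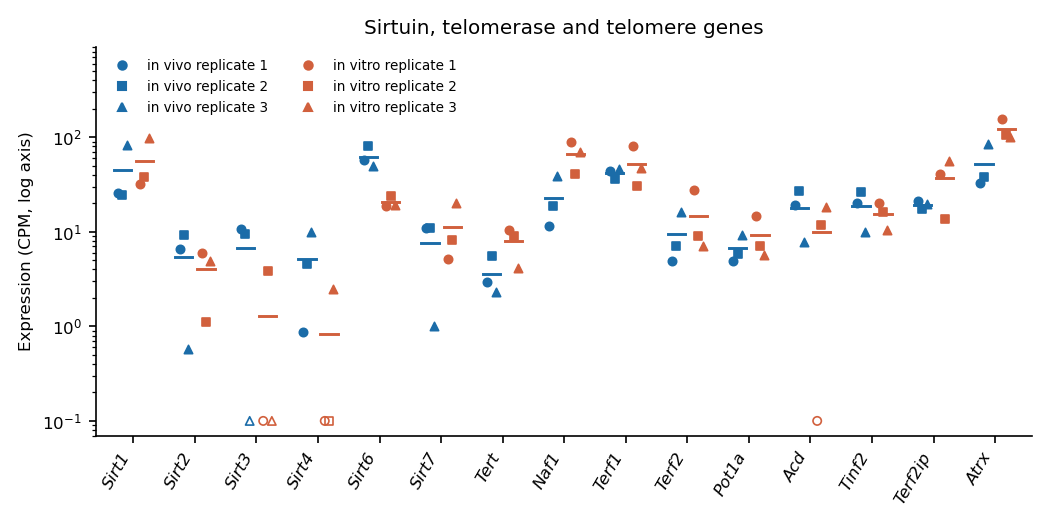
Expression of sirtuin, telomerase and telomere genes in CPM on a log axis, with 1 symbol per library, in vivo in blue and in vitro in orange, bars at group means, and open symbols at 0.1 for values below 0.1 CPM. Sirt6 is at 49.1 to 80.1 CPM in vivo and at 18.6 to 24.0 CPM in vitro, while the groups overlap for Sirt1, Sirt7, Tert and the shelterin genes.

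Among genes with an assigned symbol, a mean of at least 10 CPM and no overlap between the groups, those of smallest p with higher values in vitro were Tns3, Pank3, Tceal9, Trib1 and Ptpn3, and those with lower values in vitro were Upp1, Ppm1a, Gja1, Bhmt and Tex19.1. Tns3, which encodes a tensin of focal adhesions (chromosome 11, 8431652 to 8664758), was at 28.9 ± 8.55 CPM in vivo and 199 ± 51.3 CPM in vitro, a log2 fold change of 2.78 ± 0.38 (SE). Pank3, a pantothenate kinase of coenzyme A synthesis, was at 27.7 ± 9.03 and 155 ± 50.1 CPM. The pseudokinase gene Trib1 was at 8.16 ± 2.17 and 55.3 ± 25.9 CPM, and the tyrosine phosphatase gene Ptpn3 at 11.1 ± 1.66 and 53.5 ± 16.3 CPM (SD, n = 3 each). Tceal9 was at 1.71 ± 1.73 CPM in vivo and between 68.0 and 402.5 CPM in vitro. Upp1, the uridine phosphorylase that releases uracil from uridine, was at 211 ± 12.1 CPM in vivo and 67.4 ± 9.77 CPM in vitro (log2 fold change −1.64 ± 0.29). Gja1, a gap junction connexin, was at 591 ± 150 and 190 ± 27.5 CPM, and the phosphatase gene Ppm1a at 158 ± 26.6 and 43.6 ± 11.9 CPM. Bhmt, which methylates homocysteine from betaine, was at 499 ± 206 and 92.6 ± 47.1 CPM, and Tex19.1, which acts in transposon control, at 162 ± 73.4 and 36.1 ± 9.15 CPM. None of these 10 genes passed edgeR's test over all genes (adjusted p = 0.306 for each). Without a filter on low counts edgeR called all 10 (largest adjusted p 0.00861, for Upp1), and its newer form called Tceal9 (0.0207) and Tns3 (0.0454). All 10 were called by DESeq2, with adjusted p-values from 2.81e-07 for Tns3 to 0.00222 for Tex19.1. For Bhmt and Tex19.1, genes of similar name were also called lower in vitro by DESeq2, and counts could be shared with these.

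**Figure D3:**
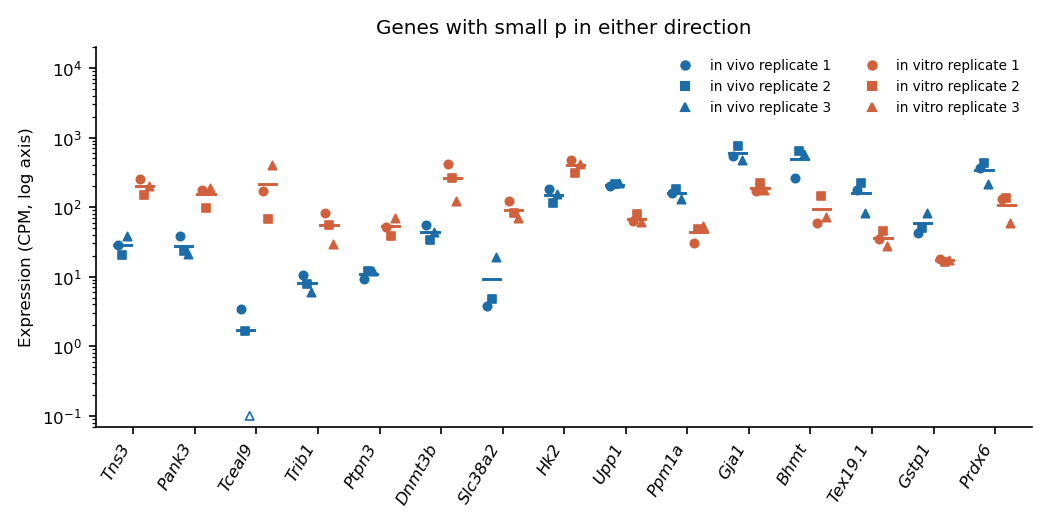
Expression of 15 genes with small p in CPM on a log axis, with 1 symbol per library, in vivo in blue and in vitro in orange, bars at group means, and open symbols at 0.1 for values below 0.1 CPM. Tns3 lies at 28.9 CPM in vivo and 199 CPM in vitro on average and Upp1 at 211 and 67.4 CPM, with no overlap between the groups.

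Counted over all genes, edgeR called 0 of 14301 genes at an adjusted p below 0.05 (smallest adjusted p 0.306), with 1458 genes at an unadjusted p below 0.05, of which 731 were higher and 727 lower in vitro. DESeq2 called 459 genes, 252 higher and 207 lower in vitro, and limma-voom with quality weights called 102, of which 75 were shared with DESeq2. Of the DESeq2 calls, 371 were among the genes edgeR tested, each with an unadjusted edgeR p below 0.05, and 69 had no counts in the lower group. The 4 calls of smallest DESeq2 p had counts in only 1 library of the higher group and were not among the genes edgeR tested. In 2762 of the tested genes (19.3%) the groups did not overlap. Chance gives 10% only if all 6 libraries are equally alike. In vivo replicates 1 and 2 were closer (Spearman correlation 0.942) than any other pair, so the share cannot show an excess due to the groups. The DESeq2 count depended on single libraries: it was 294 without in vivo replicate 1, 152 without in vivo replicate 2, 907 without in vivo replicate 3, 255 without in vitro replicate 1 and 855 without in vitro replicate 2, the library without a Y chromosome. The balance of directions also changed. Higher and lower calls in vitro were 227 and 67 without in vivo replicate 1 and 118 and 34 without in vivo replicate 2. They were 451 and 456 without in vivo replicate 3, 110 and 145 without in vitro replicate 1, and 297 and 558 without in vitro replicate 2.

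Markers of the primitive endoderm, the inner cell mass lineage that forms the yolk sac, were higher in vitro as a list. Of 22 measured markers, 21 had a positive log2 fold change, with a median of 0.94, also with Foxa2 at its lower bound, and camera with a preset correlation of 0.01 gave an adjusted p of 6.95e-07. The list did not pass with a correlation estimated from the data (adjusted p = 0.631). No marker passed edgeR's test over all genes, 5 passed adjusted over the list alone (Sox7, Foxa2, Lama1 and Fgfr2 higher, Hnf4a lower), and DESeq2 called these 5. Sox7, an endodermal transcription factor, had 1 count in the 3 in vivo libraries and 569 in the 3 in vitro libraries, a ratio of 826 with a 95% counting interval of 148 to 32689. Foxa2, another endodermal transcription factor, had 0 counts in vivo and 196, 54 and 22 counts in vitro, and was at least 132-fold higher in vitro against a floor of 3 counts over the in vivo group. Lama1, a laminin chain of the basement membrane, was at 14.7 ± 9.79 CPM in vivo and 131 ± 86.1 CPM in vitro, and the receptor gene Fgfr2 at 49.6 ± 10.8 and 118 ± 22.7 CPM (SD, n = 3 each). Hnf4a, a transcription factor of visceral endoderm and the single marker with a negative log2 fold change, was at 13.1 ± 6.17 and 1.29 ± 0.972 CPM and was named after its values were seen. The list's median was 1.70 without in vivo replicate 3 and 1.54 with limma-voom, but 0.69 without in vivo replicate 2 and 0.63 without in vitro replicate 1. The bound for Foxa2 was 46.6-fold without in vitro replicate 1, which held most of its counts, 213-fold without in vitro replicate 2 and 84.9-fold without in vivo replicate 3. The ratio for Sox7 was 422 without in vitro replicate 2, and without in vivo replicate 3, which held its 1 in vivo count, a bound of at least 178-fold remained.

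**Figure D4:**
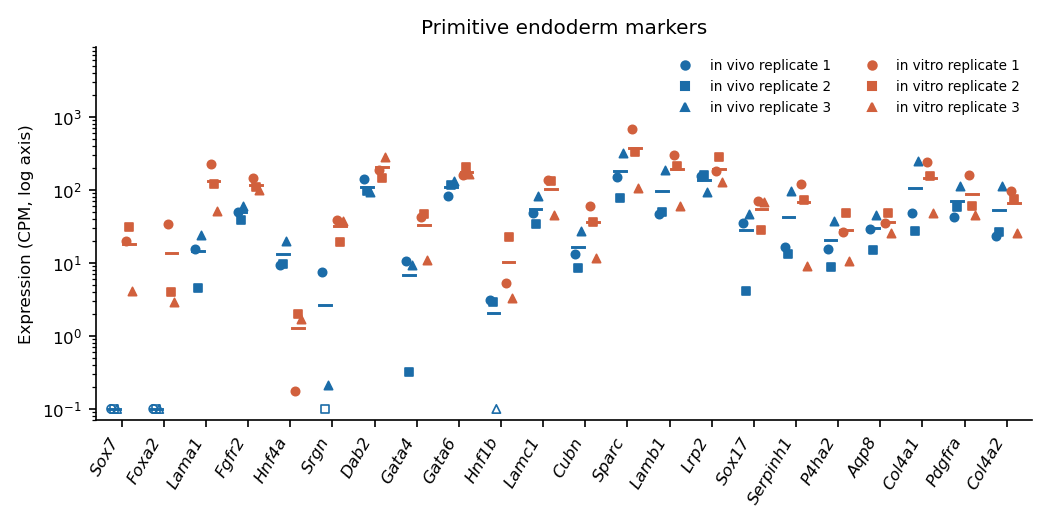
Expression of the 22 measured primitive endoderm markers in CPM on a log axis, ordered by p, with 1 symbol per library, in vivo in blue and in vitro in orange, bars at group means, and open symbols at 0.1 for values below 0.1 CPM. Sox7 and Foxa2 have 1 and 0 counts in vivo, and Hnf4a is the marker with the lower mean in vitro.

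Of 30 trophectoderm markers, genes of the outer blastocyst layer, 22 had a positive and 8 a negative log2 fold change, with a median of 0.51. Camera gave an adjusted p of 0.0318 for the list, and 0.670 with an estimated correlation. Adjusted over the list alone, 2 genes passed: Id2, an inhibitor of basic helix-loop-helix factors, at 162 ± 44.4 CPM in vivo and 589 ± 231 CPM in vitro, and Cldn6, a tight junction claudin, at 85.6, 53.8 and 19.6 CPM in vivo and 2.28, 10.5 and 2.75 CPM in vitro. Enpep was at 35.4 ± 22.2 and 123 ± 59.6 CPM and the trophectoderm transcription factor Gata3 at 127 ± 26.2 and 242 ± 44.6 CPM. The list's call was lost without in vivo replicate 2 (adjusted p = 0.106), in vivo replicate 3 (0.130) or in vitro replicate 2 (0.302). It was also lost with the stricter filter on low counts (0.0628), with protein-coding genes only (0.158) and with scaling by library totals alone (0.0781), where the median was 0.12. The median was 0.92 without in vivo replicate 1 and 0.80 without in vitro replicate 1. All 6 libraries held trophectoderm transcripts, with Gata3 at 98.3 to 275 CPM. The trophectoderm markers had a mean log2 CPM of 5.9, 5.2 and 4.6 in vivo and of 5.1, 6.2 and 5.9 in vitro (replicates 1 to 3), so the groups overlapped. Epiblast markers were at 5.6 to 6.3 per library. Trophectoderm transcripts in all 6 libraries give reason to doubt samples of inner cell mass alone, but no sample of a single lineage was compared. The means of different lists cannot be read as lineage shares, which were not measured. The epiblast and pluripotency list did not pass (26 genes, 14 positive and 12 negative, camera adjusted p = 0.630), with Sox2 at 35.2 ± 14.9 and 89.9 ± 58.4 CPM and L1td1 at 61.1 ± 6.86 and 116 ± 50.1 CPM. Immediate early genes, whose transcripts appear within minutes of a stimulus or of handling, were higher in vitro as a list (14 of 16 positive, median 1.26, camera adjusted p = 0.00135, adjusted p = 0.631 with an estimated correlation). Klf6 was at 36.6 ± 17.4 CPM in vivo and 119 ± 31.2 CPM in vitro, Jun at 0.288 ± 0.432 and 9.48 ± 5.76 CPM, and Fos at 3.43 ± 3.00 and 65.5 ± 73.8 CPM, and Klf6 passed adjusted over the list alone. This list's call was lost without in vivo replicate 3 (adjusted p = 0.0585) and with the stricter filter on low counts (0.0628), where the median was 0.61, and the median by limma-voom was 0.67. Fry's directional test called none of the lists. Its mixed test, which allows members to differ in either direction, passed for glycolysis (adjusted p = 0.00709) and for antioxidant, ATF4 and interferon genes (0.0244 each).

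**Figure D5:**
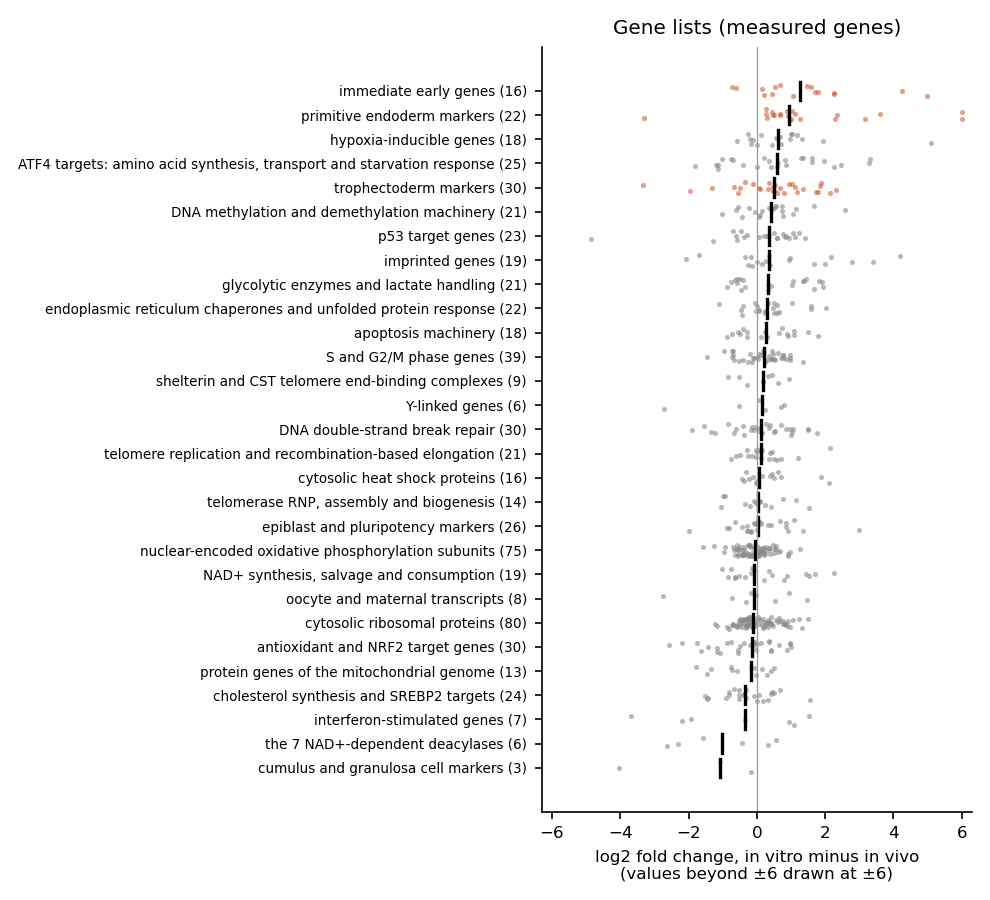
Log2 fold changes, in vitro minus in vivo, of the members of the 29 tested gene lists, with 1 point per gene, black bars at list medians, orange points for the 3 lists that camera called, and values beyond ±6 drawn at ±6. The medians are 1.26 for immediate early genes, 0.94 for primitive endoderm markers and 0.51 for trophectoderm markers.

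Genes of sugar and amino acid use and of DNA methylation included several with small p. The glycolysis list did not pass (21 genes, 12 positive and 9 negative, camera adjusted p = 0.130), and 3 genes passed adjusted over the list alone. These were the hexokinase gene Hk2 at 150 ± 33.5 CPM in vivo and 403 ± 86.2 CPM in vitro, the phosphoglycerate kinase gene Pgk1 at 10.5 ± 1.87 and 36.9 ± 12.6 CPM, and the lactate dehydrogenase gene Ldha at 23.2 ± 15.9 and 87.5 ± 35.1 CPM. Pkm, a pyruvate kinase gene, had the opposite direction (166 ± 33.0 and 97.9 ± 12.8 CPM, adjusted p = 0.455, edgeR). Among 25 targets of ATF4, a transcription factor of amino acid shortage, 17 were positive and 8 negative (camera adjusted p = 0.130, and 0.00547 without in vitro replicate 3). The amino acid transporter gene Slc38a2 was at 9.38 ± 8.76 and 92.3 ± 28.2 CPM and passed adjusted over the list alone. Slc7a1 was at 7.84 ± 6.78 and 43.5 ± 27.9 CPM, Atf4 itself at 90.0 ± 14.7 and 222 ± 138 CPM, and Eif4ebp1, a repressor of translation, at 280 ± 90.2 and 138 ± 15.4 CPM. In the DNA methylation list (21 genes, 15 positive and 6 negative, camera adjusted p = 0.130, but 0.0384 without in vivo replicate 3, 0.0440 without in vitro replicate 3 and 0.0397 with limma-voom), the de novo methyltransferase gene Dnmt3b was at 44.4 ± 10.8 and 264 ± 144 CPM and passed adjusted over the list alone, and Dppa3, which guards methylation in the early embryo, was at 655 ± 222 and 322 ± 147 CPM (adjusted p = 0.440, edgeR). The calls of the ATF4 and DNA methylation lists used the preset correlation. With all libraries and an estimated correlation, camera's adjusted p was 0.670 for each, and fry gave 0.510 and 0.355.

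Antioxidant genes and mitochondrial transcripts had members with lower values in vitro. Of 30 antioxidant and NRF2 target genes, 19 were negative and 11 positive (camera adjusted p = 0.308). The glutathione transferase gene Gstp1, at 58.4 ± 20.9 CPM in vivo and 17.2 ± 1.07 CPM in vitro, and the peroxiredoxin gene Prdx6, at 336 ± 107 and 107 ± 42.0 CPM, passed adjusted over the list alone. For both, genes of similar name were also called lower in vitro by DESeq2, and counts could be shared with these. The glutathione reductase gene Gsr was at 71.7 ± 17.2 and 31.6 ± 3.98 CPM, and Gclm, a subunit of the enzyme that makes the glutathione precursor, at 29.1 ± 21.3 and 6.32 ± 2.47 CPM. Of the 13 protein genes of the mitochondrial genome, 9 were negative and 4 positive (camera adjusted p = 0.103). Camera called this list lower in vitro in 6 other settings: without in vivo replicate 1 (adjusted p = 0.00136), in vivo replicate 2 (0.0374) or in vitro replicate 3 (0.000739), with library totals alone (0.0169), without a filter (0.0202) and with protein-coding genes only (0.0223). All 6 used the preset correlation, and with all libraries and an estimated correlation camera's adjusted p was 0.696. CYTB was at 13859 ± 3212.5 CPM in vivo and 5423 ± 2211 CPM in vitro (adjusted p = 0.358, edgeR), ND4L at 1135 ± 716 and 327 ± 139 CPM, and COX1 at 12792 ± 1391 and 7790 ± 655 CPM. Nuclear-encoded subunits of oxidative phosphorylation were 34 positive and 41 negative (camera adjusted p = 0.630, and higher in vitro at 0.0473 with a length offset), with the ATP synthase subunit gene Atp5c1 at 113 ± 34.9 and 47.9 ± 1.91 CPM (adjusted p = 0.341, edgeR). Cytosolic ribosomal protein genes were 36 positive and 44 negative, with a median log2 fold change of −0.10 and a mean of 0.03 (camera adjusted p = 0.630). Camera called this list higher in vitro without in vivo replicate 3 (adjusted p = 0.000171), with limma-voom (0.000169) and with a length offset (0.00725). These calls, and that of the oxidative phosphorylation list, used the preset correlation. With all libraries and an estimated correlation, camera's adjusted p was 0.934 for ribosomal proteins and 0.873 for oxidative phosphorylation. Rpl3 was at 76.1 ± 3.74 and 33.9 ± 12.9 CPM and Rps27a at 76.0 ± 30.4 and 178 ± 55.6 CPM, and both genes have processed copies elsewhere in the genome with which counts could be shared.

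Of the markers of other cells that a flushed or cultured embryo can carry, few had enough counts to be tested: 1 of 25 for blood and immune cells, 2 of 23 for uterine and oviduct epithelium and 3 of 24 for cumulus and granulosa cells. Laptm5, the single measured marker of blood and immune cells, was at 0.627 ± 1.09 CPM in vivo and at 102, 6.8 and 6.9 CPM in the 3 in vitro libraries (adjusted p = 0.362, edgeR), so its mean rests on in vitro replicate 1, and DESeq2 gave no adjusted p for it. Of 2 measured uterine and oviduct epithelial markers, Muc1 was at 10.2 ± 5.41 CPM in vivo and 0.984 ± 1.44 CPM in vitro (adjusted p = 0.440, edgeR), and Wfdc2, in the opposite direction, at 13.2 ± 10.3 and 27.4 ± 16.3 CPM. Of 3 measured cumulus and granulosa markers, all negative (camera adjusted p = 0.143), Amhr2, the receptor of anti-Müllerian hormone, was at 9.26 ± 3.14 and 0.514 ± 0.891 CPM (adjusted p = 0.429). Of 8 oocyte and maternal transcripts, 3 were positive and 5 negative (camera adjusted p = 0.793), with the zona pellucida gene Zp3 at 3.42 ± 1.27 and 0.465 ± 0.806 CPM and Khdc3 at 944 ± 343 and 574 ± 283 CPM. Of 27 genes of the 2-cell stage and of zygotic genome activation, 2 were measured, 1 positive and 1 negative, with Sp110 at 2.03 ± 0.998 and 1.04 ± 1.58 CPM.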

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

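Fits without ribosomal RNA genes, with a length offset or with edgeR's newer form, and the further DESeq2 fits, were chosen after the data were seen; the cause of the shifts below was not tested. The edgeR count of 0 genes became 391 without a filter on low counts (348 of them among the 14301 genes of the filtered fit), 459 with DESeq2, 102 with limma-voom and 3 with edgeR's newer form, and was 0 in the other edgeR settings, at an adjusted p below 0.1 included, and with each library left out (0 to 0). For the 5 study lists the count of 0 became 1 with DESeq2 and 3 with limma-voom and was 0 to 0 with each library left out. The log2 fold change of Sirt6 was −1.58 with DESeq2, where it passed, and −1.73 to −1.37 by edgeR with each library left out, where it did not. The count of 3 lists became 5 without a filter, 1 with the stricter filter (primitive endoderm), 7 with limma-voom, 5 with the length offset, 0 with an estimated correlation and 0 with fry, and 3 to 7 with each library left out (7 without in vitro replicate 3, 5 without in vivo replicate 1). The trophectoderm list lost its call with library totals alone and with protein-coding genes only, where the count of lists does not show it. The 459 DESeq2 calls ranged from 152 to 907 with each library left out and were 340 over the genes of edgeR's filter.

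The replicate numbers gave no pairing: deviations from group means of libraries with the same number correlated at −0.10, 0.10 and −0.04, and not every library correlated best with its own number. With the replicate number as a block, edgeR called 0 genes and 0 study genes, camera 4 lists, and DESeq2 556 genes.

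For 84 named genes, 1582 values were recomputed over all settings: 1483 kept direction and side of the threshold, 89 kept direction and passed it, and 10 values of 7 genes changed direction, none of them called. These were Terf1 (−0.0400 with library totals alone), Sirt7 (−0.15 with limma-voom), Sirt2 (0.19 with the length offset) and, with each library left out, Sirt1 (−0.34 to 1.17), Sirt2 (−0.97 to 0.16), Sirt7 (−0.20 to 0.91), Terf1 (−0.11 to 0.58), Terf2 (−0.23 to 1.28), Pot1a (−0.0557 to 0.79) and Tinf2 (−0.57 to 0.0317). Similarity within groups (median 0.809) was 0.820 by Pearson correlation and 0.824 over all genes. Depth limits Sirt5 and Terc, which no setting with a filter could test.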

Other observations

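The tests of Sirt6 against gene length and GC content and of primitive endoderm against cell share were chosen after the result was seen. Among lists not described above, imprinted genes had 13 positive and 6 negative members of 19 (camera adjusted p = 0.0778). Camera called this list higher in vitro in 8 other settings: without in vivo replicate 1 (adjusted p = 0.0405), in vivo replicate 3 (0.00267), in vitro replicate 1 (0.00363) or in vitro replicate 2 (0.0453), with library totals alone (0.0375), without a filter (0.00199), with the replicate number as a block (0.00624) and with limma-voom (0.0377). All 8 used the preset correlation. With all libraries, camera with an estimated correlation gave an adjusted p of 0.631 and fry 0.302. Jade1, a subunit of a histone acetyltransferase complex, was at 34.9 ± 16.1 CPM in vivo and 111 ± 38.2 CPM in vitro, Gab1, a signalling adaptor, at 37.3 ± 5.44 and 71.7 ± 16.6 CPM, and Peg3 at 4.09 ± 4.37 and 42.9 ± 43.9 CPM (SD, n = 3 each). Igf2, a fetal growth factor, was at 5.20 ± 3.24 CPM in vivo and at 6.8, 16.6 and 83.7 CPM in the 3 in vitro libraries. Of 18 apoptosis genes, 11 were positive and 7 negative (camera adjusted p = 0.228), among them Casp2 at 9.80 ± 1.69 and 33.8 ± 15.7 CPM and the survival genes Mcl1, at 89.4 ± 2.83 and 166 ± 3.14 CPM, and Bcl2l1, at 11.4 ± 3.47 and 31.9 ± 8.12 CPM. None of these genes passed edgeR's test over all genes or adjusted over the list alone, and DESeq2 called Jade1 (adjusted p = 0.0462) and Casp2 (0.0377).

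No gene of the remaining lists passed either adjustment by edgeR, and camera called none of them with all libraries and the settings fixed as the first choice, while DESeq2 called 1 gene, Plk2 (adjusted p = 0.0489). Hypoxia-inducible genes had a median log2 fold change of 0.62 (18 genes, 12 positive and 6 negative, camera adjusted p = 0.143), with Ndrg1 at 32.1, 114 and 392.7 CPM and Bhlhe40 at 6.8, 1.9 and 75.2 CPM in the 3 in vitro libraries. Genes of S and G2/M phase (25 of 39 positive, camera adjusted p = 0.242) included Cdt1, a licensing factor of DNA replication, at 69.8 ± 21.9 CPM in vivo and 138 ± 27.7 CPM in vitro. Double-strand break repair (17 of 30 positive, 0.533) included Brca1 at 16.8 ± 2.93 and 34.2 ± 5.76 CPM and the histone gene H2ax at 155 ± 74.2 and 66.5 ± 14.0 CPM. Targets of p53 (15 of 23 positive, 0.318) included Plk2 at 5.51 ± 7.56 and 0.189 ± 0.196 CPM, and chaperones and the unfolded protein response (15 of 22 positive, 0.171, and 0.00172 without in vitro replicate 3) included Eif2ak3 at 4.64 ± 1.21 and 19.0 ± 17.1 CPM. Heat shock proteins (8 of 16 positive, 0.308) included Hspb1 at 13.9 ± 11.6 and 51.8 ± 29.2 CPM, sterol synthesis (8 of 24 positive, 0.308) Stard4 at 7.15 ± 3.25 and 21.3 ± 9.21 CPM, and interferon-stimulated genes (3 of 7 positive, 0.630) Trim25 at 40.4 ± 14.1 and 85.4 ± 15.9 CPM. The 6 Y-linked genes had a median log2 fold change of 0.15 and a mean of −0.24 (0.308, and 0.0397 with limma-voom), with in vitro replicate 2 at 1 count. Counts assigned to Lars2, the mitochondrial leucyl-tRNA synthetase gene, named after its values were seen, made up 12.5%, 2.93% and 4.58% of all counts in the 3 in vitro libraries against 0.520%, 0.522% and 1.07% in vivo. Whether these are transcripts of the gene or reads of ribosomal RNA placed on a repeat within it was not tested.

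With 3 libraries against 3 there are 10 splits of the libraries, too few for a share under 0.05. For edgeR and DESeq2 only the real split reached its own count (1 split each), which cannot show whether chance is excluded. For lists, 9 of the 10 splits called at least as many as the real one. The count of 3 called lists thus does not set the culture apart from other groupings of these libraries. The real split gave 1458 genes at an unadjusted p below 0.05 by edgeR and the highest other split 1254, DESeq2 called 459 and 303, and camera called 3 lists and 8. The other split with the most genes for both tools joined in vitro replicate 2 with in vivo replicates 1 and 2. By edgeR, splits that kept in vivo replicates 1 and 2 together gave 467, 938, 1254 and, for the real one, 1458 genes. Those that parted them gave 145 to 259. The counts thus follow this close pair of libraries and cannot set the culture apart from it.

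Sirt6 was lower in the 3 in vitro libraries, and 3 technical explanations of the whole difference were tested. After a trend of fold changes on gene length and GC content was subtracted, its log2 fold change was −1.54 against −1.59 before (SE 0.37). Without ribosomal RNA genes and with scaling by the remaining totals it was −1.53 ± 0.38, and without in vitro replicate 2, the library lacking a Y chromosome, −1.73 ± 0.44. Each lies below 0 by more than 2 SE, which argues against these as the whole cause. All 3 tests had little room to end otherwise. Leaving out ribosomal RNA genes rescales all genes of a library by 1 factor, and library totals alone, with these genes kept, gave −1.92. Median log2 fold changes by gene length spanned only −0.32 to 0.33. In vitro replicate 2 had the highest Sirt6 of the in vitro libraries (24.0 CPM). These tests do not show a biological difference, and lower Sirt6 after culture is a hypothesis that fails edgeR's adjusted test. Chance over many genes stays open (86 genes had a p as small, where 27.7 are expected). The stage of the cultured embryos at freezing and differences in the part of the embryo sampled stay open too.

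The primitive endoderm list was higher in vitro by camera with a preset correlation (adjusted p = 6.95e-07), but did not pass with an estimated correlation (0.631) or by fry (0.302). A larger share of primitive endoderm cells with an unchanged profile, a candidate explanation, would raise the markers with at least 10 CPM in vivo by similar amounts. Cochran's Q over their fold changes (n = 17 markers, chi-square approximation) gave p = 0.00421, but 0.314 without Hnf4a, so cell share and regulation cannot be told apart here. Sox7 and Foxa2, with 1 and 0 counts in vivo, lay below the limit and did not enter Q. Q also treats the markers as independent, whereas the correlation estimated for the list was 0.338. The list's median log2 fold change was 0.68 with a length offset per library against 0.94 without. Camera with that offset gave a p of 1.31e-06 at the preset correlation. This test had little room to end otherwise, since median log2 fold changes by gene length spanned only −0.32 to 0.33. The small size of that trend, more than the test, argues against gene length as the whole cause. A later stage of the cultured embryos, differences in the part of the embryo sampled and culture itself stay open and untested.

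Longer genes had higher values in vitro: across genes with at least 10 CPM the Spearman correlation of log2 fold change with the gene length given in the count table was 0.33, and the median log2 fold change was −0.32 for genes of 67 to 1545 bases and 0.33 for genes above 5493 bases. Genes are not independent replicates in this correlation. Differences between single libraries could account for part of it, since the log2 ratio of 2 in vivo libraries correlated with length at up to 0.215 in size, against a median of 0.269, a lowest value of 0.0183 and a highest value of 0.365 for pairs across groups. The trend rests on in vivo replicates 1 and 2 (0.249 to 0.365 against the in vitro libraries), since in vivo replicate 3 gave 0.155, 0.0183 and 0.0616. The value of 0.215 lies between the lowest and the median of the pairs across groups, so library differences and the groups cannot be told apart for this trend, and no biological explanation was tested.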
